A study of Mus musculus with 2 samples.

How the data were processed

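The study profiled where the phosphatase PHLPP1 (PH domain and leucine-rich repeat protein phosphatase 1, known for removing phosphate from AKT) sat on the DNA of mouse alveolar macrophages, the resident macrophages of the lung airspaces. Per the labels' protocols, the cells came from bronchoalveolar lavage of wild-type mice, and the method was CUT&Tag, in which an antibody bound in permeabilised cells guides a transposase that cuts and tags nearby DNA. An antibody against PHLPP1 and a commercial CUT&Tag kit were used, per the labels' protocols. One group was left untreated and the other received interleukin-4 (IL-4) at 20 ng/ml for 4 h. Each of the 2 groups held 1 library, so there were no replicates and no test between the groups was possible.

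Each library came with 1 list of peak regions, and the lists were called per library. Bowtie 0.12.8, MACS2 2.2.7.1, DiffBind and the mm10 build are named per the submitters' processing notes, which give no roles or order for them. The settings, the filters and any control library were not given in the sources used here. The fold enrichment in the deposited lists is the authors' own ratio of the pileup at the summit to the background their caller estimated for that library, and it is not scaled between libraries. The authors' lists also hold a −log10 p and a −log10 q per region, both against that same background. The integer score in the deposited lists equalled 10 times the −log10 p, cut to a whole number, for 100% of regions. The summit offset in the deposited lists is the distance in bp from the region's start. No −log10 p lay below 2.00 in the untreated list or 2.03 in the IL-4 list, as a p limit of 0.01 would give, and no limit on q was visible. Within a list no regions overlapped. Fold and −log10 q served to describe, rank or filter regions within a list, and numbers of regions past a fold limit were set side by side. Fold and p also gave the pileups that the closing section compares between the libraries, which are not scaled for depth.

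The depth in reads is not stated. Because MACS adds 1 to the pileup and to the background before dividing, the fold and p of a region together give back both. The pileups recovered this way were whole numbers within 0.05 for 100% of regions in each list. The constant background, which grows with sequencing depth and fragment length, was 13.9 fragments in the untreated library and 15.9 in the IL-4 library, a ratio of 1.14. It was the background of 68.7% of untreated regions and 54.2% of IL-4 regions, within 0.1%; the others had a higher local background. Intervals are exact Clopper-Pearson 95% intervals of shares and cover counting error only. Intervals of ratios of region numbers were computed on the log scale from Poisson counts, with the same limit.

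Regions on the 19 autosomes, X and Y were used. Regions were called overlapped when they shared at least 1 bp with the other list, and the share expected by chance came from shifting one list along each chromosome 100 times. The gene table used was RefSeq on GRCm38.p6, the assembly behind mm10, with 21883 protein-coding genes on these chromosomes. That table gives no strand, so the planned window around the transcription start was replaced by a window of 1 kb around either end of a gene, and a gene with a region in it is called marked. A marked end can be the start or the finish of the gene. The exon, intron and UTR positions of regions were not analysed here.

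The 14 gene lists, the 1 bp overlap, the 1 kb window and the −log10 q limit of 5 were set before the data were examined. Of 337 list entries, 336 matched a gene symbol, and 2 genes stood in 2 lists. Each list was set against 10000 random lists of equal size, as a percentile that describes these libraries. Random lists that tied with the real list were split evenly between below and above. For genes marked in the IL-4 library alone, the random lists held as many genes marked in the untreated library as the real list. This matching was chosen after the data were seen, in place of the planned matching on promoter GC content, which needs a genome sequence. A scan of 14 sequence patterns at summits also needs the sequence and was not run.

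Named genes followed a rule with 4 parts. Phlpp1, Stat6, Arg1, Retnla, Chil3, Mrc1, Il4ra, Irf4, Klf4, Pparg and Csf1r were always named. From each list came up to 4 genes marked in 1 library alone, those with the highest −log10 q. The last parts took the 5 regions of highest fold in each library, and the 10 of highest fold in each library alone with the nearest protein-coding gene. Some genes that this rule names are not reported here. Any other gene or family named was chosen after its values were seen.

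Alternatives covered stricter −log10 q and fold limits, equal list lengths, other overlap rules, other windows, other gene sets and other random lists. The computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots in matplotlib 3.10.9. Overlap and gene-end calls were tested on simulated regions against a direct comparison, and 0 of 2000 overlap calls differed. The background solved from simulated folds was off by at most 0.00213% in 19385 regions made like the untreated list. Of 200 null gene lists, 3.0% lay above the 97.5th percentile.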

Results

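The data were 2 CUT&Tag libraries made with an antibody against PHLPP1 from mouse alveolar macrophages, 1 untreated and 1 given IL-4, the cytokine that drives alternative activation of macrophages. The comparison asks which DNA PHLPP1 occupied with and without IL-4. The untreated list held 165968 regions and the IL-4 list 226476, over backgrounds of 13.9 and 15.9 fragments. There were no replicates, so the differences below describe these 2 libraries and carry no p-value. No library made with a control antibody was analysed here, so signal that does not come from PHLPP1 could not be separated.

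Counting every region of the lists, most protein-coding genes were marked in both libraries, and more of them in the IL-4 library. In the untreated library 12582 of 21883 protein-coding genes (57.5%, 95% interval 56.8 to 58.2) had a region within 1 kb of an end, and in the IL-4 library 15413 (70.4%, 69.8 to 71.0). Both libraries marked 11915 genes, the IL-4 library alone 3498 and the untreated library alone 667. At a −log10 q of at least 5, the untreated library marked only 32.9% of genes and the IL-4 library 51.7%. Phlpp1 itself carried a strong region in each. Arg1 and Retnla, classical IL-4 response genes of macrophages, were marked in the IL-4 library alone, Retnla by a weak region. For Arg1 this rests on the 1 kb window, since a stronger region 2.59 kb past the same end was present in both libraries.

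Shifted regions marked 24.1% of genes in the untreated library and 31.1% in the IL-4 library, so the observed numbers were 2.38 and 2.27 times those of shifted regions. At a −log10 q of at least 5, the untreated library marked 7193 genes and the IL-4 library 11313, with 4265 in the IL-4 library alone and 145 in the untreated library alone. That limit does not cut both lists at equal strength. A fold of 2.62 at Cd14 carried a −log10 q of 4.85 in the untreated library, while 2.61 at Ptgs2 carried 5.91 in the IL-4 library. At a fold of 3 or more the untreated library marked 5723 genes and the IL-4 library 8772. A gene marked in 1 library alone often had a region of the other library close by. Of the 3498 genes marked in the IL-4 library alone, 2165 (61.9%, 60.3 to 63.5) had an untreated region within 5 kb of an end, and for 135 (3.86%, 3.25 to 4.55) the IL-4 region at the end itself overlapped an untreated region that stopped short of the window. Of the 667 genes marked in the untreated library alone, 460 (69.0%, 65.3 to 72.5) had an IL-4 region within 5 kb of an end.

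Phlpp1 (chromosome 1, 106171869 to 106394245, mm10) had its strongest end region at 106171200 to 106171902 in the untreated library, with a fold of 8.65, and at 106171170 to 106171871 in the IL-4 library, with a fold of 10.3. These ranked 115 of 14296 and 132 of 20279 among the gene-end regions of their lists. All folds given here are the authors' own values per region, each against the background of its own library. Irf4, a transcription factor of alternative activation, had a region at its lower end (chromosome 13, 30748948 to 30749492 in the untreated library) with folds of 3.75 and 5.81. Stat6, the transcription factor that IL-4 receptors activate, was listed at 2.88 and 4.21, and Il4ra, the receptor chain for IL-4, at 2.78 and 3.29. Klf4, another factor of alternative activation, was listed at 3.88 and 3.86, and Mrc1, the mannose receptor CD206, at 2.21 and 2.79. Pparg, a nuclear receptor that alveolar macrophages need to develop, was listed at 2.15 and 3.32. Csf1r, the receptor for the growth factor CSF1, was listed at 2.95 and 2.79. Chil3, the chitinase-like protein Ym1, had no region within 1 kb of an end in either library. Strong regions in general were higher in the IL-4 library, so a higher fold there does not by itself set one of these genes apart. At shared regions of fold 4 or more in the untreated list, the median pileup ratio was 1.41 to 1.64 across the autosomes. The ratio of the constant backgrounds was 1.14. Of the end regions named in this paragraph, only that of Phlpp1 reached an untreated fold of 4. Whether the other genes rose more than regions of like strength was not tested.

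**Figure D1:**
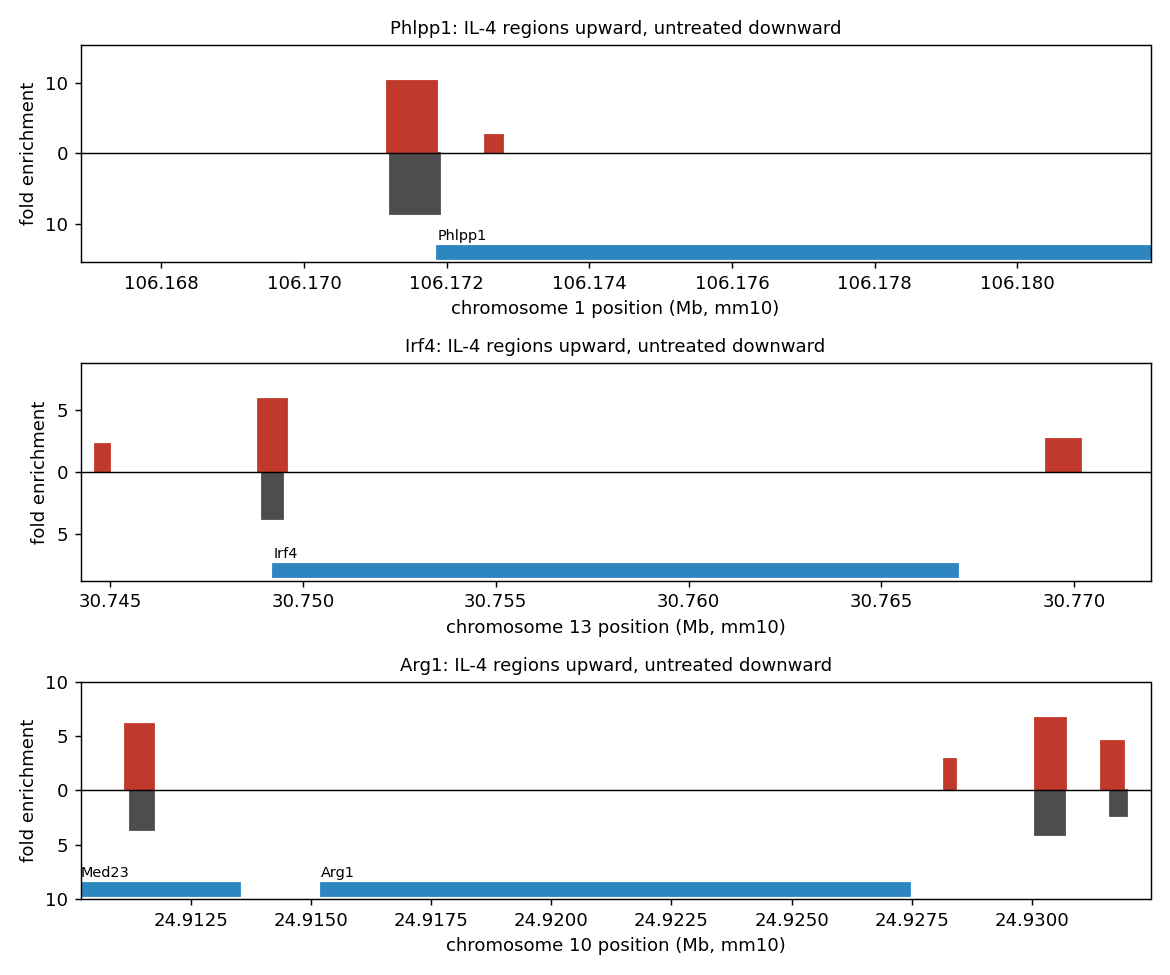
Regions around Phlpp1, Irf4 and Arg1, with position in Mb on mm10 along the horizontal axis and fold enrichment on the vertical axis, IL-4 regions drawn upward in red and untreated regions downward in grey, and genes as blue bars. Phlpp1 and Irf4 have an end region in both libraries, while the region 0.706 kb above Arg1 is in the IL-4 library alone and its neighbours are in both.

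Of the 30 genes known to respond to IL-4 or to act in alternative activation, 16 were marked in the untreated library and 24 in the IL-4 library. The 8 genes marked in the IL-4 library alone were Fn1 (fibronectin, fold 3.62), Clec10a (a galactose-type lectin receptor, 3.38), Mgl2 (its close paralog, 3.02), Arg1 (arginase 1, 2.90), Cd209d (a lectin receptor, 2.19), Retnla (the secreted protein RELMα, 1.96), Ccl24 (an eosinophil-attracting chemokine, 1.96) and Egr2 (a transcription factor, 1.66). None was marked in the untreated library alone. The regions of Cd209d, Retnla, Ccl24 and Egr2 had a −log10 q of 1.40 to 3.26, so these 4 genes were marked in neither library at a −log10 q of at least 5. The nearest untreated regions lay 22.9 kb from Retnla, 24.2 kb from Ccl24, 21.3 kb from Cd209d, 22.7 kb from Mgl2, 6.14 kb from Clec10a and 4.72 kb from Fn1, measured to the nearer end. At Arg1 (chromosome 10, 24915207 to 24927470) the region at 24928177 to 24928431 was in the IL-4 library alone. A stronger region 2.59 kb past the same end, at 24930061 to 24930692 in the untreated library, was present in both, with folds of 4.16 and 6.69. At Egr2 a stronger untreated region (fold 2.63) began 1.53 kb from the end.

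Of the 14 list genes that the untreated library left unmarked, the IL-4 library marked 8 (57.1%, 28.9 to 82.3), against 3498 of 9301 (37.6%, 36.6 to 38.6) of all such genes. Random lists with as many unmarked genes gave a median of 5 and a central 95% range of 2 to 9, which put the list at percentile 92.4. The percentile was 97.6 at a −log10 q of at least 5 and 69.1 with equally long lists, where 5 of the 14 genes were marked.

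Genes of the macrophage itself were marked almost completely in the IL-4 library. All 26 genes of alveolar macrophage identity were marked there and 22 in the untreated library. The 4 genes marked in the IL-4 library alone were Ctsk (cathepsin K, 2.66), Abcg1 (a cholesterol exporter, 2.41), Fabp1 (a fatty acid binding protein, 2.29) and Krt79 (a keratin, 1.91). Untreated regions lay just outside the window at 3 of these, 1.28 kb from Ctsk (fold 2.88), 1.52 kb from Fabp1 (2.87) and 1.299 kb from Krt79 (2.55). At Krt79 the untreated region lay at the opposite end of the gene from the IL-4 region. Of 24 genes shared by macrophages in general, 17 were marked in the untreated library and 23 in the IL-4 library. Irf8 (a transcription factor of the myeloid lineage, 4.03), Fcgr1 (a high-affinity IgG receptor, 3.02), C1qb (a complement subunit, 2.46) and Itgam (the integrin CD11b, 2.43) were among the 6 marked in the IL-4 library alone.

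Interferon target genes were marked at 12 of 23 in the untreated library and 20 in the IL-4 library. Cxcl10 (a chemokine, 3.83), Bst2 (the antiviral protein tetherin, 3.68), Nos2 (inducible nitric oxide synthase, 2.98) and Ifit1 (an antiviral protein, 2.96) led the 8 marked in the IL-4 library alone. The Ifit1 region also lay at an end of Ifit1bl2.

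These macrophage and interferon lists had the 3 highest of the 14 percentiles for genes marked in the IL-4 library alone, and were picked out after all were seen, at 99.1 for alveolar macrophage identity, 99.4 for macrophages in general and 98.9 for interferon targets. With unmatched random lists the first 2 fell to 49.3 and 87.5, and with a 5 kb window to 77.9 and 90.5, while the interferon list stood at 98.8 and 99.1. With matched lists, the highest percentile a list could reach depended on how many of its genes were unmarked, so the 14 values share no common scale. All 4 unmarked genes of alveolar macrophage identity were marked in the IL-4 library, so that list could not have exceeded its 99.1.

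Other pathways of the macrophage were already marked at most genes without IL-4. Of 25 genes of the PI3K, AKT and PHLPP pathway, 20 were marked in the untreated library and 24 in the IL-4 library. Pik3cg (a PI3K catalytic subunit of leukocytes, 3.02), Rictor (a subunit of mTOR complex 2, 2.73) and Foxo1 (a transcription factor that AKT inhibits, 2.49) were among those marked in the IL-4 library alone. An untreated region of slightly higher fold (2.55) lay 1.68 kb from the same end of Foxo1. Inflammatory NF-κB genes were marked at 20 and 21 of 24, with Traf1 (a signalling adaptor, 1.83) in the IL-4 library alone. Lysosome and autophagy genes were marked at 21 and 23 of 24, with the IL-4 library alone marking Mcoln1 (a lysosomal calcium channel, 3.44) and Becn1 (an autophagy initiator, 3.38). The Mcoln1 region also lay at an end of Pnpla6, and it overlapped an untreated region (fold 3.15) that lay 1.17 kb from the gene's end, just outside the window. Lipid and fatty acid oxidation genes were marked at 21 and 23 of 24, with the IL-4 library alone marking Ppargc1a (a coactivator of mitochondrial genes, 2.32) and Ppara (a nuclear receptor for fatty acids, 2.19). A stronger untreated region (2.82) lay 2.07 kb from an end of Ppara. The percentiles of these lists for genes marked in the IL-4 library alone were 96.2, 33.2, 81.8 and 81.8.

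Genes active in all cells were marked at 22 of 24 in both libraries. Hprt (a purine salvage enzyme, 3.32) was marked in the IL-4 library alone and Ldha (lactate dehydrogenase A, 2.15) in the untreated library alone. A stronger IL-4 region (2.37) lay 1.985 kb from the same end of Ldha. Neuron genes were marked least, at 7 and 8 of 24. Pvalb, Mog, Syn1 and Rbfox3 were marked in the IL-4 library alone, and Stmn2, Slc6a3 and Th in the untreated library alone, all with folds of 1.81 to 3.02. The Rbfox3 region also lay at an end of Engase. A stronger IL-4 region (2.85) lay 1.39 kb from an end of Stmn2.

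Markers of other lung cells were also marked at more genes in the IL-4 library. Lung epithelium genes were marked at 12 and 17 of 24, among them the adhesion genes Cdh1 (2.12) and Epcam (2.02), Krt18 (2.01) and the water channel Aqp5 (1.83) in the IL-4 library alone, and the surfactant gene Sftpd (2.35) in the untreated library alone. A stronger untreated region (2.72) lay 1.33 kb from an end of Aqp5. Lymphocyte genes were marked at 10 and 17 of 24, with Ebf1 (a B cell factor, 3.26), Lck (a T cell kinase, 2.67), Blk (2.31) and Cd3g (2.13) in the IL-4 library alone and Bcl11b (2.79) in the untreated library alone. Granulocyte genes were marked at 8 and 13 of 20, with Csf3r (the G-CSF receptor, 3.14), Ngp (2.61), Ly6g (2.19) and Padi4 (2.14) in the IL-4 library alone and Mpo (myeloperoxidase, 1.94) in the untreated library alone. A stronger IL-4 region (2.59) lay 1.99 kb from an end of Mpo. Fibroblast and endothelium genes were marked at 6 and 11 of 20, with Vwf (2.96), Col1a1 (2.72), Pdgfra (2.36) and Cldn5 (2.05) in the IL-4 library alone and Fbn1 (2.35) and Emcn (2.01) in the untreated library alone. The Cldn5 region also lay at an end of Cdc45. Counting every region, the IL-4 library marked 8 of 14 unmarked genes in the lymphocyte list, as many as in the IL-4 response list. The percentiles of the epithelium, lymphocyte, granulocyte, fibroblast and endothelium, neuron and constitutive lists for such genes were 80.4, 92.4, 80.4, 82.3, 12.2 and 62.5. At a −log10 q of at least 5, the IL-4 library alone marked 5 of 24 lymphocyte genes but 10 of 30 IL-4 response genes. At that limit the untreated and IL-4 libraries marked 4 and 8 lymphocyte genes and 3 and 7 epithelium genes. They marked 3 and 6 granulocyte genes and 1 and 6 fibroblast and endothelium genes.

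**Figure D2:**
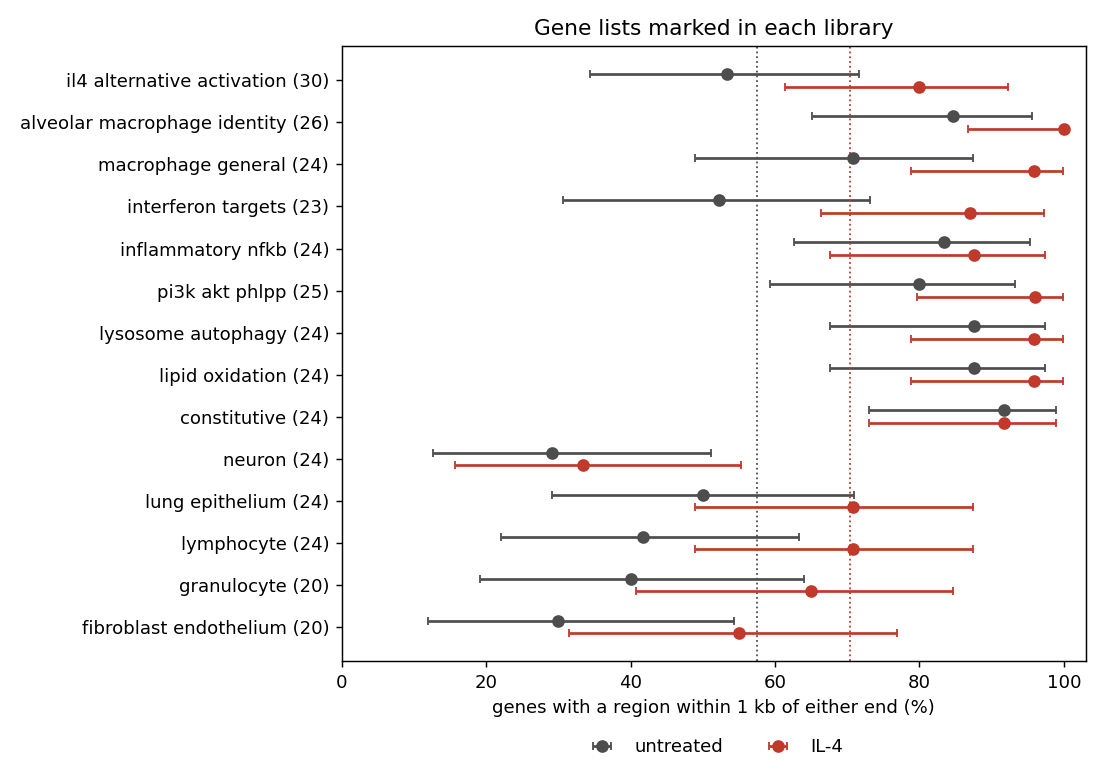
Percent of the genes of each of the 14 lists with a region within 1 kb of an end, with grey points for the untreated library, red points for the IL-4 library, bars for exact 95% intervals and the number of genes in brackets. The dotted lines stand at 57.5% and 70.4%, the values of all protein-coding genes in the untreated and IL-4 libraries, and neuron genes lie lowest among the lists in the untreated library.

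Strong regions lay at the same places in both libraries, and the regions of the IL-4 library alone were mostly weak. All 2462 untreated regions of fold 5 or more overlapped an IL-4 region, and 6226 of 6241 IL-4 regions of that fold (99.8%, 99.6 to 99.9) overlapped an untreated region. Over the whole lists the overlap was 62.9% of untreated regions (62.7 to 63.2) and 45.6% of IL-4 regions (45.4 to 45.8), against 6.86% and 5.03% with shifted regions. The IL-4 list was 1.36 times as long as the untreated list, 1.94 times at a fold of 3 or more and 2.53 times at a fold of 5 or more, while 50 untreated and 47 IL-4 regions reached a fold of 20. The median width was 300.0 bp in the untreated list and 327 bp in the IL-4 list, and the median fold 2.15 and 2.19.

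**Figure D3:**
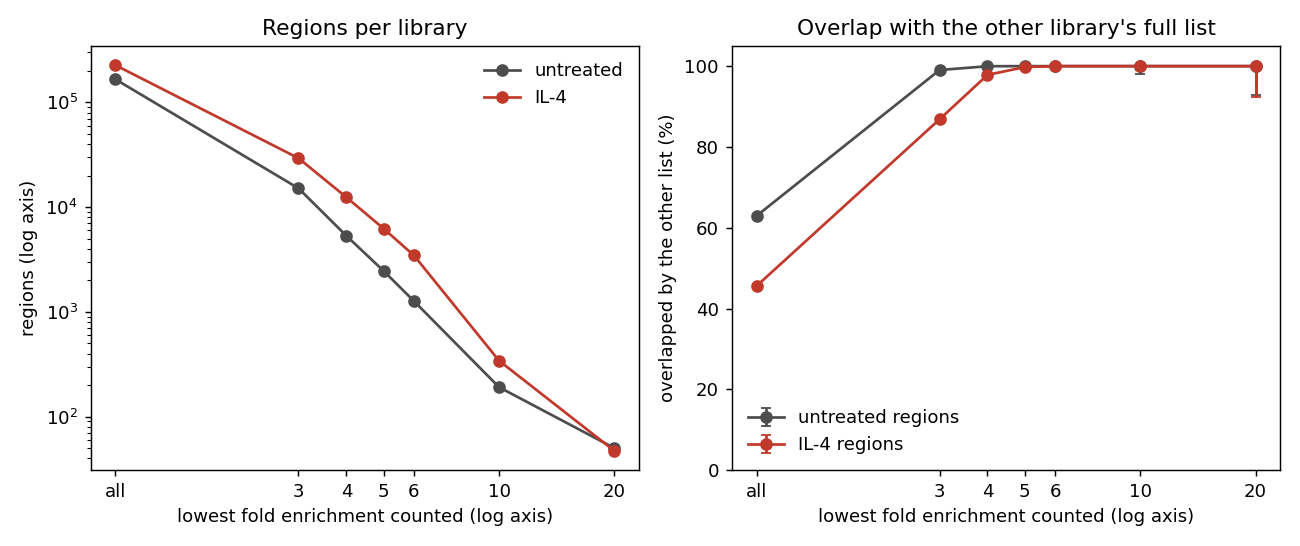
Left, the number of regions per library (log axis) against the lowest fold enrichment counted (log axis). Right, the percent of those regions that overlap any region of the other list, with exact 95% intervals, which is 62.9% and 45.6% over all regions and 100% in both libraries from a fold of 6.

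Gene ends held 8.61% of untreated regions (8.48 to 8.75) and 8.95% of IL-4 regions (8.84 to 9.07), against 3.61% and 3.73% with shifted regions. The order of the libraries turned at a fold of 3 or more, where the shares were 33.3% and 27.8%, and at a −log10 q of at least 5, where they were 23.0% and 16.7%. Regions at gene ends, inside genes and outside genes within 100 kb were 1.42, 1.49 and 1.45 times as many in the IL-4 list. Regions farther than 100 kb from any protein-coding gene numbered 33183 in the untreated list and 31846 in the IL-4 list, 0.960 times as many.

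The 10 regions of highest fold were the same in both libraries, with folds of 36.1 to 42.2. The highest lay inside Chl1 (a neural adhesion gene) on chromosome 6, 103648990 to 103649412 in the untreated library, with folds of 41.8 and 42.2. The next lay outside genes, 102.7 kb from Csf2ra on chromosome 19, 137 kb from Rab10 on chromosome 12, 90.5 kb from B230307C23Rik on chromosome 16 and 7.34 kb from Tmem196 on chromosome 12, with folds of 40.4 to 41.5 in the untreated library. The local background of these 10 regions was at least 3.20 times the constant background, and only 1 of them in each library lay at a gene end. Regions prone to mapping artefacts, such as repeats collapsed in the assembly, were not removed here, and whether these 10 are such regions was not tested.

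The strongest regions found in the IL-4 library alone lay mostly inside genes. Their highest was on chromosome 14 at 79445366 to 79445990, 5.84 kb from Kbtbd6, with a fold of 5.99. The next, on chromosome 10 at 87787512 to 87787953, lay 70.3 kb from Igf1, the growth factor gene, with a fold of 5.87. Of the 10, 7 lay inside a gene, namely Nup62 (5.83), Zfp608 (5.81), Slc6a6 (5.52), Rbak (5.45), Sobp (5.28), Cdyl (5.22) and Enox1 (5.22), and the Rbak region was at the gene's end. The last lay 5.97 kb from Rplp1, with a fold of 5.13. Of all 123206 regions in the IL-4 library alone, 54787 lay inside a gene away from its ends and 7974 at a gene end.

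In the untreated library alone, the 10 strongest regions were weaker, with folds of 3.62 to 4.22, and 1 lay inside a gene, Bbip1. Others lay nearest to Mrln (2.57 kb), Sfi1 (17.1 kb), Fam174a (117 kb), Zfp521 (130 kb), 4930583I09Rik (159 kb), Mat2b (330.4 kb), Gabrg1 (358 kb) and Gm20810 (362 kb). Of all 61507 regions in the untreated library alone, 22763 lay inside a gene away from its ends and 1869 at a gene end.

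Chromosome X held few regions in both libraries. It had 4.47 regions per Mb in the untreated library and 5.64 in the IL-4 library, against 67.1 and 91.6 on the autosomes. Of 966 X-linked protein-coding genes, 16.0% (13.8 to 18.5) were marked in the untreated library and 26.7% (23.9 to 29.6) in the IL-4 library, against 60.1% and 73.3% of autosomal genes. Over all regions, chromosome 19 had the highest ratio of IL-4 to untreated regions among the autosomes, 2.11, followed by chromosome 11 with 1.85, and the others had at most 1.53. At a fold of 3 or more chromosome 19 did not stand apart, with 2.19 against 2.21 on chromosome 11.

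**Figure D4:**
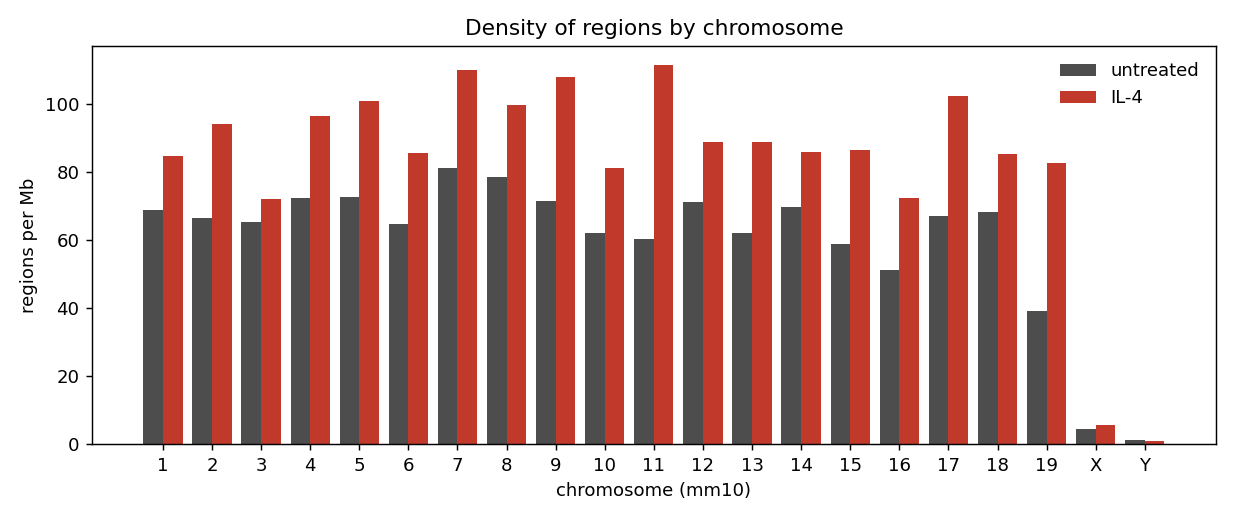
Regions per Mb (vertical axis) on each chromosome of mm10 (horizontal axis), with grey bars for the untreated library and red bars for the IL-4 library. The bars of chromosome X stand at 4.47 and 5.64, and that of chromosome 19 in the untreated library, at 39.1, is the lowest among the autosomes.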

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

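The fold limits, the random lists matched on gene length and the removal of genes with shared ends were chosen after the data were seen, as was the main matching of random lists on untreated marking; the other settings were planned. The direction of the ratio of IL-4 to untreated regions held under each setting run here (though not among the 50 untreated and 47 IL-4 regions of fold 20 or more): 1.36 became 2.41 at a −log10 q of at least 5, 1.29 with regions within 1 kb merged, 1.94 at a fold of 3 or more and 2.53 at a fold of 5 or more. The overlapped share of untreated regions (62.9%) and IL-4 regions (45.6%) became 80.5% and 33.3% at a −log10 q of at least 5, 53.6% and 52.6% with equal numbers of regions, 48.3% and 35.4% when 50% of both regions had to overlap, 54.4% and 39.8% for summits within 200 bp, and 99.0% and 86.8% at a fold of 3 or more in the counted list. The share at a gene end (8.61% and 8.95%) became 23.0% and 16.7% at a −log10 q of at least 5, 5.31% and 5.12% with a 200 bp window, 18.7% and 21.5% with 5 kb, 14.0% and 14.5% with all annotated genes, and 33.3% and 27.8% at a fold of 3 or more, so the libraries changed order under the q, fold and 200 bp settings; with equal numbers the IL-4 share was 10.4%. Marked genes fell from 12582 to 7193 in the untreated library at a −log10 q of at least 5, and to 5723 and 8772 at a fold of 3 or more; in the IL-4 library (15413) they were 11313 at that −log10 q and 14254 with equal numbers, and the libraries had 17114 and 18701 with a 5 kb window and 9452 and 11906 with 200 bp. The percentile of the IL-4 response list (92.4) became 97.6 at a −log10 q of at least 5, 69.1 with equal numbers, 96.3 with a 5 kb window, 93.4 with unmatched and 83.3 with length-matched random lists. The causes of these moves were not tested. A given −log10 q can stand for a lower fold in the IL-4 library, so that limit does not cut both lists at equal strength. The motif scan and the matching on GC content were not run. With 1 library per group, depth and treatment cannot be varied apart, and no paired analysis was possible because each group held 1 library.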

Other observations

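The ratio of backgrounds and a percentile for the IL-4 response list were planned, but the matching behind that percentile, the bounds set for both and all other tests in this part were chosen after the results were seen. The gene families were also picked after the lists were seen. Of 73 cytosolic ribosomal protein genes, 63 were marked in the untreated library (86.3%, 76.2 to 93.2) and 72 in the IL-4 library (98.6%, with a lower 95% bound of 92.6). Mitochondrial ribosomal protein genes were marked at 78.2% and 91.0% of 78, proteasome genes at 80.4% and 89.1% of 46, and respiratory complex I genes at 75.5% and 91.8% of 49. All 23 genes of the vacuolar proton pump were marked in the IL-4 library and 17 in the untreated library. The libraries marked 57 (55.3%, 45.2 to 65.1) and 69 (67.0%, 57.0 to 75.9) of the histone genes, with intervals that hold the shares of all protein-coding genes (57.5% and 70.4%). They marked genes named Zfp, for zinc finger proteins, at 66.2% and 84.9% of 397. Receptor families of the nose were the least marked of the protein-coding families taken, with 19.9% and 23.96% of 1110 olfactory receptor genes and 8.78% and 7.93% of 353 vomeronasal receptor genes. Keratin genes were marked at 37.7% and 67.9% of 53, but at 5.66% and 17.0% at a −log10 q of at least 5. Transfer RNA genes were marked at 45.6% and 57.8% of 408, and small nuclear RNA genes at 11.9% and 16.5% of 1004. On chromosome Y, Eif2s3y, a translation factor gene, was marked in both libraries, with folds of 2.21 and 3.08, and Ddx3y, an RNA helicase gene, in the IL-4 library alone, with a fold of 2.49, while Kdm5d and Uty were marked in neither. Chromosome Y held 116 untreated and 86 IL-4 regions, a ratio of 0.741, the lowest of the chromosomes and the only one under 1.

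The IL-4 library held more regions, and 3 explanations were set against this. Deeper sequencing as the whole cause is argued against, since the list was 2.33 times as long (2.26 to 2.41) at a fold of 4 or more, while the background differed by 1.14 times. A larger share of signal over background in the IL-4 library is a candidate explanation. At shared regions of fold 4 or more in the untreated list the median pileup ratio ran from 1.41 (bootstrap interval 1.35 to 1.46) to 1.64 over the autosomes, above that background ratio on each. Of the IL-4 regions of fold 4 or more, 97.8% overlapped an untreated region. The pileup ratio therefore largely restates the larger number of strong regions and is no separate support. Recruitment to IL-4 response genes stays open as a hypothesis, because the list's percentile of 92.4 lay between the bounds set for it. With 1 library per group, an effect of IL-4 on signal over the whole genome and a better yield of that library cannot be told apart.

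The scarcity of regions on chromosome X was set against 2 explanations. A low gene density is argued against, since the 4 autosomes about as gene-poor as X had at least 12.8 times its regions per Mb. A single X copy in male donor mice would lower the pileup there, so X at a given fold was set beside the autosomes at a fold 2 times as high, over 4 such pairs in each library. The ratio of densities ran from 0.946 to 1.43 in 7 of the 8 pairs and was 2.27 (1.69 to 3.04) in the IL-4 library for a fold of 5 on X, with an interval that crosses the bound of 2. A single copy therefore stays open. The pairs covered only X regions of fold 2.5 or more, which were 234 of 763 in the untreated library and 406 of 963 in the IL-4 library. The sex of the mice was not given in the sources used here. The Y-linked gene Eif2s3y was marked in both libraries and Ddx3y in the IL-4 library alone, as male donors would allow. Kdm5d and Uty were marked in neither, so these genes do not settle the sex.

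Over all regions chromosome 19 had the largest ratio of IL-4 to untreated regions among the autosomes. It stood apart among weak regions, with a ratio of 2.11 under a fold of 2.5 (1.80 on chromosome 11). The ratio was 2.19 at a fold of 3 or more (2.21 on chromosome 11) and 2.63 at a fold of 6 or more (3.35 on chromosome 15). Under a fold of 2.5 the untreated library held 26.7 regions per Mb on chromosome 19, against at least 39.0 on the other autosomes. The IL-4 library held 56.3, within the autosomal range of 52.0 to 83.8, so the untreated library was short of weak regions on chromosome 19. A gain near genes as the cause is argued against, since regions more than 100 kb from any gene were 1.76 times as many there (1.504 to 2.058), and at most 1.26 times on any other autosome. Fewer reads from the whole chromosome in the untreated library stays open: at shared regions of fold 4 or more in the untreated list the median pileup ratio was 1.64 (bootstrap interval 1.57 to 1.67, from 1000 resamples), next to the highest of the other autosomes, also 1.64. Chromosome 7, with that same pileup ratio, had only 1.35 times as many IL-4 regions, so the pileup ratio does not single out chromosome 19. The share of chromosome 19 regions above the constant background was 15.7% in the untreated library, the lowest of the autosomes, and 40.7% in the IL-4 library. Over the autosomes, the gain in that share and the ratio of regions had a Spearman correlation of 0.835 (0.770 without chromosomes 11 and 19). These values go with fewer reads there but do not decide the question. No biological explanation was tested.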
